A study of Mus musculus with 14 samples.

How the data were processed

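RNA was measured by sequencing in brown adipose tissue (BAT) of male mice, 14 libraries in 4 groups set by genotype and temperature. WT at 30 °C and AdC3KO at 30 °C had 3 libraries each, and WT at 4 °C and AdC3KO at 4 °C had 4 each. The grouping came from the genotype and treatment labels, and the number in each sample title named the replicate. The labels do not say outright that each library is a separate animal, so p-values measure the spread between these libraries, and no time of tissue collection is given in the sources used here.

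RNA was extracted with TRIzol and RNeasy columns with DNase treatment, and libraries were made with the NEBNext Ultra II RNA kit at GENEWIZ, per the labels' protocols. The authors trimmed reads with Trimmomatic, inspected them with FastQC, aligned them to GRCm38/mm10 with STAR, counted reads per gene with HTSeq and tested the counts with DESeq2, per the series' design text. Versions, the annotation release, the strand setting and the treatment of reads that align to several places are not given in the sources used here. The deposited values are whole-number counts of reads per Ensembl gene, not normalised, with 55471 genes in 1 table of the 14 libraries. The same table carries 5 summary lines that name no gene. These were left out of library sizes and tests, and 3 of them were 0 in every library. Reads outside any gene amounted to 5.95% to 8.19% of a library and reads that fell on more than 1 gene to 5.53% to 6.03%. Symbols were taken from the reference annotation by exact Ensembl identifier, which named 55144 identifiers (99.41%).

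Gene counts summed to between 19.9 M and 29.0 M (M, counts in units of 1e6) per library, with group means of 22.3 ± 2.25 M for WT at 30 °C and 24.4 ± 1.91 M for AdC3KO at 30 °C (SD, n = 3 each), and 22.4 ± 2.61 M for WT at 4 °C and 26.6 ± 1.73 M for AdC3KO at 4 °C (SD, n = 4 each). The protocol names no molecular identifiers, so counting intervals and floors cover counting error only. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Every pair of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 16.9 to 83.6 over genes with at least 20 counts, so each library was counted once.

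Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group at its minimum count of 10, which left 15949 genes for testing. Library sizes were scaled by TMM, with factors between 0.822 and 1.21, and the common biological coefficient of variation was 0.20. All 14 libraries entered a single quasi-likelihood fit of the 4 group means, with robust estimation of the spread. Differences were tested with the quasi-likelihood F-test of edgeR, and p-values were adjusted by the Benjamini-Hochberg method at 0.05 over all tested genes. Every adjusted p given for a gene comes from this test unless DESeq2 is named. Expression is given as counts per M (CPM) with the TMM factors, as mean ± SD, and log2 fold changes carry their standard error (SE). The 5 comparisons were AdC3KO against WT at each temperature, 4 °C against 30 °C in each genotype, and the genotype by temperature interaction, which is the cold response of AdC3KO minus that of WT.

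A total of 32 gene lists of 8 to 75 genes, of which 5 to 75 were tested, covered thermogenesis, lipid and glucose metabolism, mitochondria, stress responses, signalling, the circadian clock and markers of cell types that BAT or its dissection can include. Calls within a list are counted over all tested genes and, separately, adjusted over the list alone. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with camera at an estimated correlation. They were also tested with fry, which sets a list against no change and not against other genes, so that its p answers another question. The lists, the tests, the groups and the rule for naming genes were fixed before the data were examined. The rule names the Clstn3 locus, 9 thermogenic or lipid droplet genes in every comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap and whose higher group averages at least 5 CPM, and up to 4 called members of each list, or the 2 most abundant when none was called. Genes without a regular symbol and pseudogenes are counted only, unless fewer than 10 genes pass. Not every gene that the rule names is given in the text. A gene outside this rule is said to have been chosen after its values were seen.

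The edgeR step was run on counts simulated from the real means and library sizes, with 200 genes of 1 CPM or more changed by known folds. It recovered, at 1.5-, 2- and 4-fold, 20.9%, 67.2% and 93.9% of changed genes for AdC3KO against WT at 30 °C (15510 genes tested), 37.3%, 61.2% and 87.9% at 4 °C (15474 genes), 35.8%, 74.6% and 95.5% for cold in WT (15477 genes), 35.8%, 77.6% and 95.5% for cold in AdC3KO (15454 genes) and 7.46%, 50.7% and 87.9% for the interaction (15524 genes). In the same order 8 of 129, 3 of 127, 10 of 147, 6 of 145 and 1 of 98 calls were of unchanged genes.

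Alternatives planned beforehand were DESeq2 1.42.0, other scaling (median ratio and upper quartile), no filter beyond 1 count in any library, a stricter filter at 5 CPM, a test against a 1.2-fold change, a fit of the compared groups alone, the replicate numbers as a block, the skeletal muscle list as a covariate, a surrogate variable (sva 3.50.0), omission of mitochondrially encoded genes, and leaving out each library in turn. Alternatives added after seeing the data left out the 2 libraries highest in interferon genes, the 5 libraries with skeletal muscle transcripts, or the genes of chromosomes 6, 9 and 16. Sequence matches of pseudogenes to their parent genes used BLAST 2.17.0. Regional counts, exact tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are on GRCm38.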

Results

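Brown adipose tissue (BAT), a fat depot specialised in producing heat, was profiled by RNA sequencing in wild-type mice (WT) and in mice that lack Clstn3b in adipocytes (AdC3KO). Clstn3b is a product of the Clstn3 locus that the series title links to lipid droplet size and heat production. All mice were males 10 weeks old that had been kept at thermoneutrality (30 °C), where little heat production is needed, for 2 weeks. Part of each genotype was then moved to 4 °C for 6 h. There were 3 WT and 3 AdC3KO libraries at 30 °C and 4 WT and 4 AdC3KO libraries at 4 °C, with 19.9 M to 29.0 M gene counts each (M, 1e6 counts). The first principal component of expression, with 70.7% of the variance, separated the temperatures, and the second carried 7.26%.

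The knockout was read out first at its own locus. Clstn3 (ENSMUSG00000008153, protein coding, minus strand of chromosome 6 from 124430759 to 124464794) had fewer counts in every AdC3KO library than in any WT library. It averaged 207 ± 23.2 CPM in WT and 15.8 ± 1.31 CPM in AdC3KO at 30 °C (SD, n = 3 each), which is 13.1-fold lower. At 4 °C it averaged 1109.6 ± 97.4 CPM in WT and 65.8 ± 11.9 CPM in AdC3KO (SD, n = 4 each), which is 16.9-fold lower. The log2 fold change was −3.71 (SE 0.16, adjusted p = 1.13e-09) at 30 °C and −4.08 (SE 0.14, adjusted p = 2.87e-11) at 4 °C. Two-sided exact permutation tests of the CPM values gave p = 0.1 at 30 °C and p = 0.0286 at 4 °C, each the smallest these group sizes allow. The locus was higher at 4 °C than at 30 °C in WT (log2 fold change 2.42, SE 0.14, adjusted p = 8.49e-10), and so were the counts left in AdC3KO (2.05, SE 0.14, adjusted p = 4.79e-09). The annotation joins the locus into 1 gene, so Clstn3b and full-length Clstn3 transcripts were not separated.

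**Figure D1:**
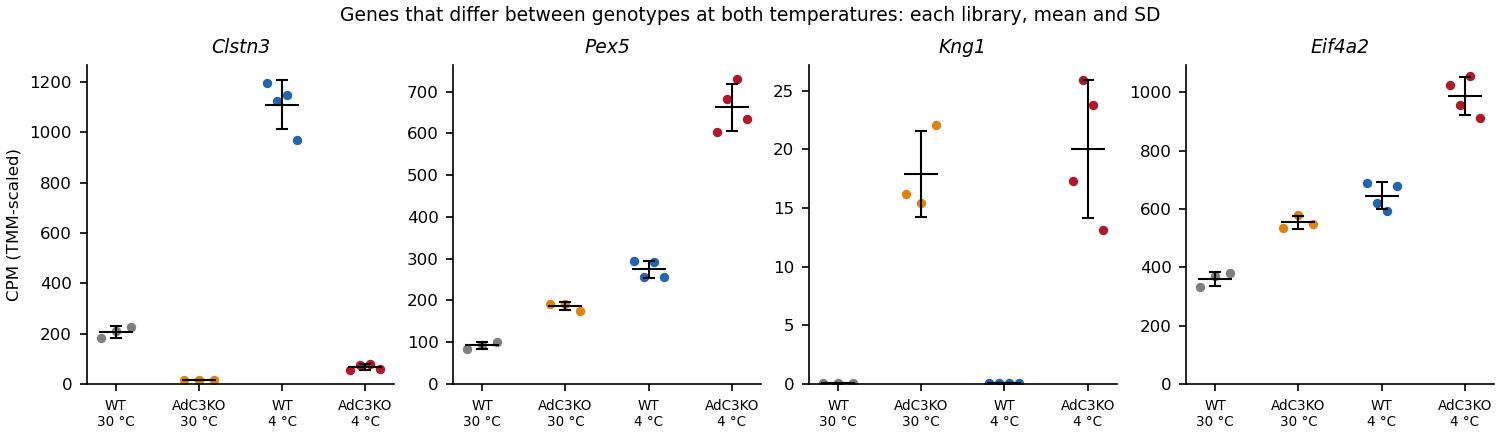
CPM (TMM-scaled, vertical axes from 0) of Clstn3, Pex5, Kng1 and Eif4a2 in each library (points), with the mean and SD of each group (bars; n = 3 at 30 °C, n = 4 at 4 °C). Clstn3 was lower and the other 3 genes were higher in every AdC3KO library than in any WT library of the same temperature.

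Without a cold stimulus, at 30 °C, the transcriptomes of AdC3KO and WT BAT differed in few genes. Pex5, the receptor that carries enzymes into peroxisomes, averaged 186 ± 9.16 CPM in AdC3KO against 92.5 ± 9.15 CPM in WT (SD, n = 3 each). Kng1, which encodes kininogen, the precursor of bradykinin, was close to undetected in WT, with 6 counts over the 3 libraries, and averaged 17.9 ± 3.65 CPM in AdC3KO. Eif4a2, an RNA helicase of translation initiation, was 554 ± 23.4 CPM in AdC3KO and 360.2 ± 24.5 CPM in WT. Transcripts of the thermogenic and lipid droplet machinery did not pass the test.

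Of 15949 genes, 6 were higher and 1 lower in AdC3KO at 30 °C, with 212 genes at an unadjusted p below 0.05. DESeq2 called 8, including all 7, and its additional gene was Zfp949, a zinc finger gene on chromosome 9. The log2 fold change was 1.01 for Pex5 (SE 0.10, adjusted p = 0.000227), 7.76 for Kng1 (SE 0.38, adjusted p = 5.57e-09) and 0.62 for Eif4a2 (SE 0.10, adjusted p = 0.0217). Ankdd1a, on chromosome 9, averaged 0.144 CPM in WT and 1.88 CPM in AdC3KO (log2 fold change 3.67, SE 0.55, adjusted p = 0.0142). The other calls were the processed pseudogenes Gm11868 (log2 fold change 4.67, adjusted p = 0.00125) and Gm7049 (3.79, adjusted p = 0.00373), whose sequences match Cyb5r4 at 97.98% and Me1 at 98.43%, so that reads can be shared with those genes. The libraries of the groups did not overlap for any of the 7, where chance gives 10% of genes, and for 7.29% of all tested genes. Pex5 and Clstn3 are neighbours on chromosome 6, Kng1 and Eif4a2 lie on chromosome 16 between 23057865 and 23114136, and Eif4a2 overlaps Rfc4 on the opposite strand.

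Expression of the uncoupling protein Ucp1 was 1618 ± 370.1 CPM in AdC3KO and 1625 ± 216 CPM in WT at 30 °C (log2 fold change −0.01, SE 0.17). Among the lipid droplet proteins, the log2 fold change was −0.00 for Cidea (SE 0.15), 0.07 for Cidec (SE 0.20) and 0.03 for Plin1 (SE 0.17). It was 0.29 for the coactivator Ppargc1a (SE 0.24), 0.22 for the thyroid hormone deiodinase Dio2 (SE 0.18), −0.45 for the fatty acid elongase Elovl3 (SE 0.54) and −0.41 for S100b (SE 0.23), which encodes a calcium-binding protein linked to sympathetic innervation of fat. The hormone gene Fgf21 had 7 counts in each group. Each of these had an adjusted p of 1.

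No member of the 32 lists was called at 30 °C over all genes, and 1 member was called lower adjusted over the list alone, among mitochondrially encoded subunits. By camera, 3 lists were lower in AdC3KO. Mitochondrially encoded subunits had a mean log2 fold change of −0.80 and a median of −0.09 (adjusted p = 5.2e-05, and adjusted p = 0.974 with an estimated correlation). Their most abundant members were mt-Co1, with a log2 fold change of 0.08 (SE 0.20), and mt-Cytb, with −0.09 (SE 0.18), while copies of mitochondrial sequence in the nuclear genome can share reads of the others. Endothelial markers had a median of −0.15 (adjusted p = 0.00635, and adjusted p = 0.974 with an estimated correlation), with the vascular endothelial growth factor receptor Kdr at −0.23 (SE 0.11) and the cadherin Cdh5 at −0.17 (SE 0.14). Interferon response genes had a median of −0.44 (adjusted p = 0.0272, and adjusted p = 0.974 with an estimated correlation), with Bst2 at −0.34 (SE 0.85). The endothelial call was lost without WT library 1 (0.704) or 3 (0.113) or AdC3KO library 2 (0.313) at 30 °C. The interferon call was lost without WT library 1 (0.277) or 3 (0.0848) or AdC3KO library 3 (0.161) at 30 °C, and without WT library 2 (0.0838) or AdC3KO library 2 (0.0575), 3 (0.0513) or 4 (0.0659) at 4 °C. After adjustment over the lists no estimated-correlation p was below 0.974, and the lowest adjusted p by fry, against no change, was 0.995. Skeletal muscle transcripts, which can enter a dissection of interscapular fat, were present in WT library 3 (mean log2 CPM of the list 3.36) and AdC3KO libraries 1 (2.35) and 2 (1.59), against −1.23 to −1.11 in the other 3.

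The count at 30 °C fell from 7 to 4 without WT library 1 and to 4 without WT library 3. The call of Eif4a2 was lost without any 1 of the 6 libraries at 30 °C, with a log2 fold change of 0.57 to 0.66 (adjusted p from 0.0669 to 0.268, and from 8.9e-10 to 1 over all alternatives). That of Ankdd1a was lost without WT library 1, 2 or 3 or AdC3KO library 2 or 3, with 3.49 to 3.78 (0.124 to 0.216, and 2.2e-05 to 1 over all alternatives), and that of Gm7049 without WT library 1 (3.62, adjusted p = 0.063) or 3 (3.73, adjusted p = 0.0616), its range over all alternatives being 1.1e-06 to 1. The count at 30 °C was 4 with a filter at 5 CPM and 2 (Gm11868 and Gm7049) without the genes of chromosomes 6, 9 and 16. Without the 5 libraries of either temperature with muscle transcripts, AdC3KO at 30 °C keeps 1 library, so no count is given.

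After 6 h at 4 °C the difference between genotypes again rested on few genes, and most of them were those seen at 30 °C. Pex5 averaged 663 ± 55.7 CPM in AdC3KO and 275 ± 20.5 CPM in WT, Kng1 20.01 ± 5.86 CPM in AdC3KO against 6 counts over the 4 WT libraries, and Eif4a2 987 ± 65.5 CPM in AdC3KO and 645 ± 45.5 CPM in WT (SD, n = 4 each). Zfp949 was 10.1 CPM in AdC3KO and 5.59 CPM in WT. Ucp1 reached 13734 ± 1703 CPM in AdC3KO and 12686 ± 1202 CPM in WT, which was within the spread between libraries.

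At 4 °C 7 genes were higher and 1 lower in AdC3KO, with 765 at an unadjusted p below 0.05. DESeq2 called 22, including all 8. The log2 fold change was 1.27 for Pex5 (SE 0.09, adjusted p = 1.09e-06), 7.99 for Kng1 (SE 0.34, adjusted p = 7.45e-10), 0.61 for Eif4a2 (SE 0.08, adjusted p = 0.00446) and 0.84 for Zfp949 (SE 0.12, adjusted p = 0.00781). The remaining calls were Gm11868 (4.82, adjusted p = 0.000103), Gm7049 (3.69, adjusted p = 0.000491) and Gm44007, a transcript beside Pex5 that averaged 8.16 CPM in AdC3KO and 0.254 CPM in WT (5.06, adjusted p = 0.00339). Ankdd1a had a log2 fold change of 1.79 and an adjusted p of 0.963. The groups did not overlap for any of the 8, where chance gives 2.86% of genes, and for 2.27% of all tested genes. Both temperatures shared 5 higher genes and 1 lower gene, where independent calls would share 0.003 and 6.27e-05.

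The fixed thermogenic and lipid droplet genes did not pass the test at 4 °C, with adjusted p from 0.963 to 0.994. The log2 fold change was 0.11 for Ucp1 (SE 0.15), 0.34 for Ppargc1a (SE 0.20), 0.11 for Dio2 (SE 0.14), 0.06 for Cidea (SE 0.13) and 0.38 for Elovl3 (SE 0.23). It was −0.32 for Cidec (SE 0.18), −0.20 for Plin1 (SE 0.14), 0.04 for Fgf21 (SE 0.28) and 0.05 for S100b (SE 0.20).

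**Figure D2:**
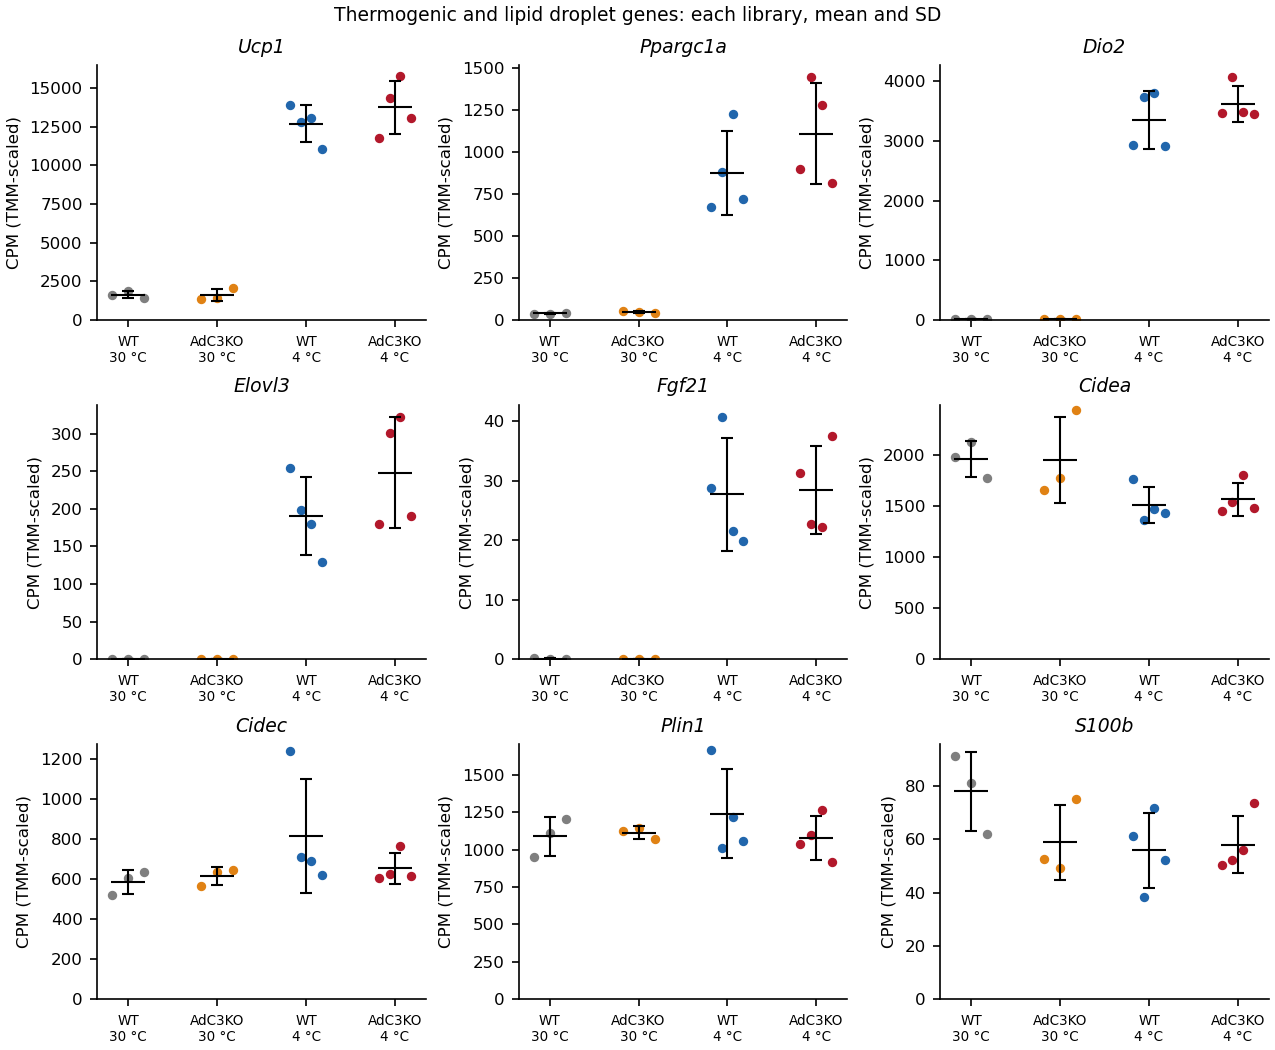
CPM (TMM-scaled, vertical axes from 0) of 9 thermogenic and lipid droplet genes in each library (points), with the mean and SD of each group (bars; n = 3 at 30 °C, n = 4 at 4 °C). The genotypes overlap at 4 °C for all 9, and Ucp1 averaged 12686 CPM in WT and 13734 CPM in AdC3KO.

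No list member was called at 4 °C over all genes, and 1 was higher adjusted over the list alone, among cyclic AMP and immediate early genes. Camera called 9 lists, none of which passed with an estimated correlation after adjustment (adjusted p of at least 0.298), and the lowest adjusted p by fry, against no change, was 0.286. Nuclear oxidative phosphorylation subunits were higher, with a median log2 fold change of 0.16 (adjusted p = 3.06e-11, and adjusted p = 0.693 with an estimated correlation), the ATP synthase subunits Atp5b and Atp5a1 being at 0.07 and 0.09. Tricarboxylic acid cycle genes were higher (adjusted p = 0.00814, and adjusted p = 0.693 with an estimated correlation), with Ogdh at 0.07. Glycolysis and glucose uptake genes were higher (adjusted p = 0.013, and adjusted p = 0.693 with an estimated correlation), with Aldoa at 0.10 and Eno1 at −0.08. Red blood cell transcripts were higher (adjusted p = 0.00591, and adjusted p = 0.693 with an estimated correlation), with Hbb-bs at 0.28 and Hba-a1 at 0.34, paralogous globin genes that can share reads. Leaving out 1 library at 4 °C ended 3 of these 4 calls. It ended that of the tricarboxylic acid cycle without WT library 2 (0.185) or 4 (0.381) or AdC3KO library 3 (0.132), that of glycolysis without WT library 2 (0.206) or AdC3KO library 3 (0.0578), and that of red blood cell transcripts without WT library 4 (0.24).

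Lower lists at 4 °C included white adipocyte markers, with a median of −0.55 (adjusted p = 0.0013, and adjusted p = 0.298 with an estimated correlation), among them the hormone leptin (Lep) at −1.47 and the natriuretic peptide receptor Npr3 at 0.21. Macrophage markers had a median of −0.45 (adjusted p = 0.000384, and adjusted p = 0.693 with an estimated correlation), with Lyz2 at −0.45 and C1qb at −0.42. Lipolysis genes were lower (adjusted p = 0.00591, and adjusted p = 0.693 with an estimated correlation), with the triglyceride lipase Pnpla2 at 0.02 and Prkar2b, a regulatory subunit of protein kinase A, at −0.39. De novo lipogenesis genes were lower (adjusted p = 0.0198, and adjusted p = 0.693 with an estimated correlation), with Scd1 at −0.35 and Fasn at −0.50. Fibroblast and extracellular matrix genes were lower (adjusted p = 0.013, and adjusted p = 0.693 with an estimated correlation), with Sparc at −0.11 and Col3a1 at −0.30. Leaving out 1 library at 4 °C ended the macrophage call without WT library 4 (0.106) and the lipolysis call without WT library 1 (0.193). It ended the lipogenesis call without WT library 3 (0.24) or AdC3KO library 2 (0.0856) or 3 (0.164), and the fibroblast call without WT library 1 (0.3) or AdC3KO library 1 (0.249) or 4 (0.162). Skeletal muscle transcripts were present in AdC3KO library 3 (mean log2 CPM of the list 4.65) and WT library 2 (1.54), against −1.65 to −1.30 in the others. Interferon genes were high in WT library 4 (6.25) and AdC3KO library 1 (4.77), against 2.40 to 3.72 in the others.

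The count at 4 °C was 5 with a filter at 5 CPM, 5 in a fit of the compared groups alone, 3 without the libraries with muscle transcripts and 2 without the genes of chromosomes 6, 9 and 16. Leaving out the libraries high in interferon genes gave 9. The call of Zfp949 was lost without WT library 3 (log2 fold change 0.81, adjusted p = 0.0564, and 6.5e-07 to 0.459 over all alternatives). Leaving out 1 library at a time lost none of the other 7, and moved the fold by over 1.5 times for Gm11868 (5.94) and Gm7049 (4.31) without WT library 4 and Gm44007 (5.67) without WT library 1 at 4 °C.

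**Figure D3:**
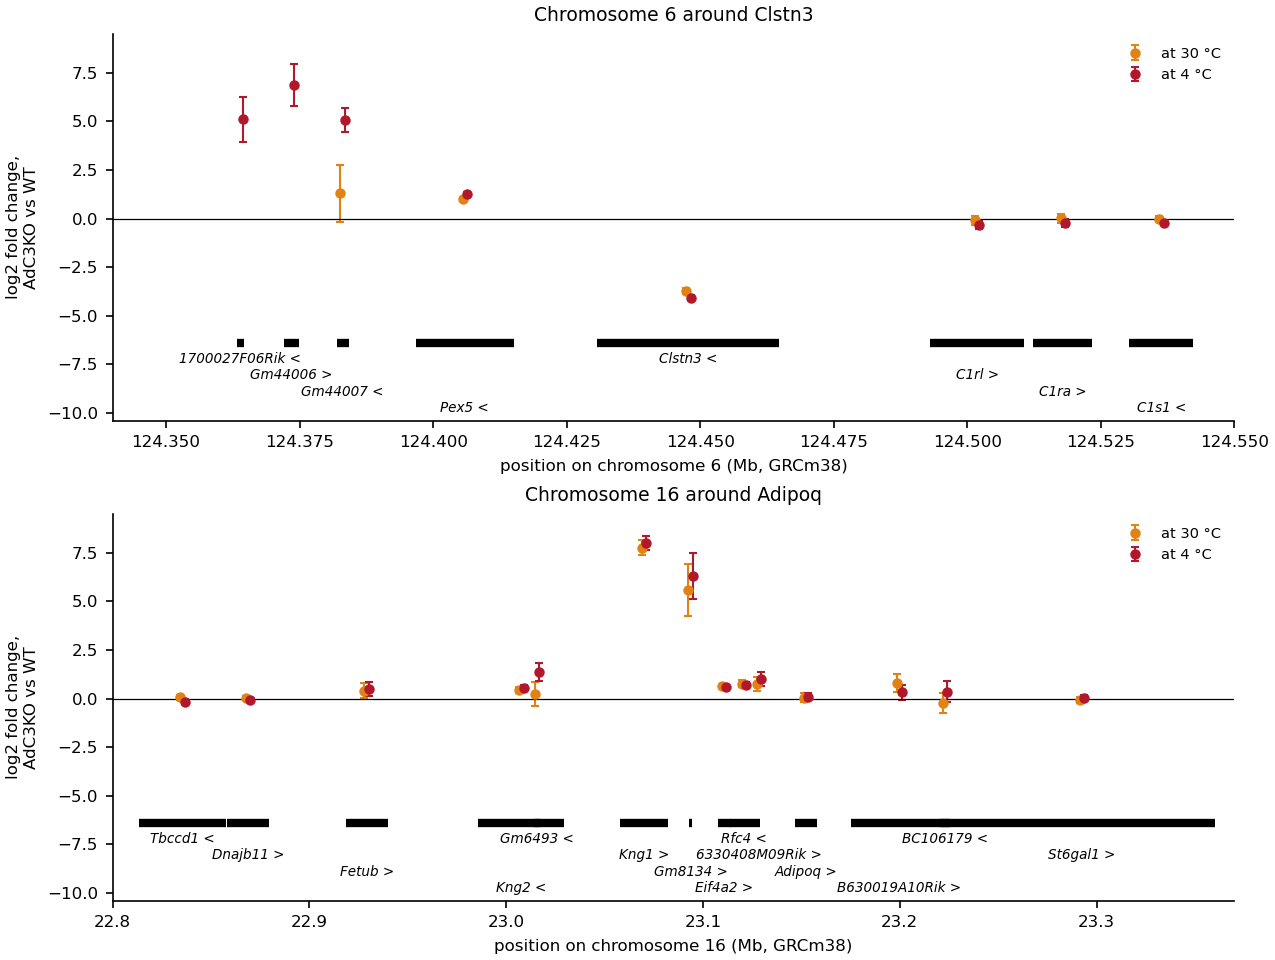
Log2 fold change of AdC3KO against WT (points, bars are SE) of tested genes along chromosome 6 around Clstn3 and chromosome 16 around Adipoq (GRCm38 positions in Mb, black bars are genes, arrowheads give the strand), at 30 °C (orange) and 4 °C (red). Genes with 0 counts in both groups have no point, and Pex5 (1.01 and 1.27) and Kng1 (7.76 and 7.99) were higher at both temperatures while Clstn3 was lower.

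Exposure to 4 °C for 6 h changed most of the expressed genes of WT BAT. Ucp1, which uncouples respiration to make heat (chromosome 8, 83290352 to 83298452), was 7.81-fold higher at 12686 ± 1202 CPM (SD, n = 4) than at 30 °C, where it was 1625 ± 216 CPM (SD, n = 3). Dio2 went from 14.8 to 3344 ± 488 CPM, Ppargc1a from 38.6 to 875 ± 251 CPM and the lipid droplet coat protein Plin2 from 298 to 4400.3 CPM. Lep fell from 142 ± 67.1 to 2.79 ± 0.845 CPM, and Dgat2, an enzyme of triglyceride synthesis, fell from 1783 ± 239 to 258 ± 54.2 CPM. Most genes of the cyclic AMP, protein stress, fatty acid oxidation and lysosome lists rose, and most genes of lipogenesis that passed the test fell, while after adjustment no list differed by camera with an estimated correlation (lowest adjusted p 0.155) and 19 of 32 did by fry, against no change, with the 7 called at the preset correlation among them.

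In WT 4879 genes were higher and 4908 lower at 4 °C, of which 2226 and 2923 by at least 2-fold. Members of the lists given below with a log2 fold change and no SE passed the test over all genes. The groups did not overlap for 9081 of them and for 60.3% of all tested genes, where chance gives 5.71%. DESeq2 called 10126 genes and shared 9628. The median log2 fold change of all genes was −0.03, and upper-quartile scaling moved it to −0.27, with 3640 genes higher and 6415 lower (36.2% higher against 49.9%), so small changes are relative to the scaling.

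The largest rises in WT, those of Mfsd2a and Acot5, began from few counts. Mfsd2a, a transporter of lysophosphatidylcholine, had 2 counts at 30 °C and 10849 at 4 °C, a ratio of depth-scaled counts of 5158 with a counting interval of 1427 to 42594. Acot5, a peroxisomal acyl-CoA thioesterase, had 0 counts at 30 °C and was at least 323-fold higher. Next were the organic anion transporter Slco1a1 (log2 fold change 8.28, SE 0.61), Fgf21 (8.18, SE 0.56), Elovl3 (7.89, SE 0.39), Dio2 (7.82, SE 0.22), the nuclear receptor Nr4a3 (7.69, SE 0.62), Bean1 (6.70), the dopamine receptor Drd1 (6.61) and the kinase Sgk2 (6.53), each with an adjusted p of at most 6.73e-07. The largest falls were in the cytokine Ctf1 (−6.59, SE 1.32, 4 counts at 4 °C), Lep (−5.68, SE 0.53), the apelin receptor Aplnr (−5.68, SE 0.26), Klhdc7a (−5.04), the bone morphogenetic protein family member Gdf5 (−5.03), the protein kinase A anchor Akap5 (−4.92), the lactate receptor Hcar1 (−4.91), Tmem25 (−4.54), Bahcc1 (−4.28) and Samd5 (−4.04). Their adjusted p was at most 0.00093. Leaving out 1 library moved the fold by over 1.5 times for Fgf21 (9.35 without WT library 1 and 7.56 without WT library 3 at 30 °C), Sgk2 (7.38 without WT library 3 at 30 °C), Ctf1 (−7.97 without WT library 2 at 4 °C) and Akap5 (−5.83 without WT library 1 at 4 °C), with Mfsd2a and Acot5 given by their counts alone. Of the 6931 eligible genes, 324 lacked a regular symbol.

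Of 24 genes of the thermogenic list, 15 rose and 4 fell in WT, with the same counts adjusted over the list alone (camera adjusted p = 0.00306, and adjusted p = 0.395 with an estimated correlation). Ucp1 (log2 fold change 2.96, SE 0.18, adjusted p = 1.11e-09), Ppargc1a (4.50, SE 0.27, adjusted p = 4.64e-09) and the glycerol kinase Gk (5.42, SE 0.16, adjusted p = 9.44e-13) rose. The lipid droplet protein Cidea fell (−0.38, SE 0.14, adjusted p = 0.0264), a call that was lost without WT library 1 or 2 at 30 °C or WT library 2, 3 or 4 at 4 °C (−0.37 to −0.31, adjusted p from 0.0563 to 0.109, and from 0.000696 to 0.134 over all alternatives). Of 24 cyclic AMP and immediate early genes, 20 rose and none fell, and 21 rose adjusted over the list alone (adjusted p = 1.04e-06, and adjusted p = 0.155 with an estimated correlation). They included the growth arrest gene Gadd45g (5.29), the kinase Sik1 (4.08), the phosphatase Dusp1 (3.39) and the transcription factor Atf3 (5.63), each with an adjusted p of at most 7.95e-09. S100b had a log2 fold change of −0.48 (SE 0.21, adjusted p = 0.0658).

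Lipid genes moved in both directions. Of 18 lipid droplet proteins 10 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.104). Plin2 (3.88, SE 0.16), Fitm2 (1.76), which promotes droplet formation, and the GTPase Rab18 (0.84) rose and Plin3 fell (−2.42, SE 0.08), each with an adjusted p of at most 2.69e-07. Cidec, which fuses droplets, rose slightly (0.47, SE 0.19, adjusted p = 0.0421), and Plin1 had a log2 fold change of 0.19 (SE 0.16, adjusted p = 0.315). The call of Cidec was lost in 10 of 14 fits without 1 library (adjusted p from 0.0511 to 0.173, and from 0.00831 to 0.300 over all alternatives), namely any at 30 °C and, at 4 °C, WT library 1, which left a log2 fold change of 0.19, and AdC3KO libraries 1, 2 and 4. In triglyceride synthesis 10 of 16 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.719 with an estimated correlation). Gk, the acyltransferases Dgat1 (2.20, SE 0.14) and Gpam (1.83, SE 0.13) rose, while Dgat2 fell (−2.79, SE 0.16). In de novo lipogenesis 2 of 20 rose and 12 fell, also adjusted over the list alone (adjusted p = 0.0704). The regulators Srebf1 (−3.30), Mlxipl (−2.12) and Mid1ip1 (−2.16) fell, as did Pnpla3 (−2.03). In lipolysis 5 of 18 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.869), with a median of 0.18 that turns negative under upper-quartile scaling and a mean of −0.00. Abhd5, the activator of the triglyceride lipase, rose (2.06) with the phosphodiesterase Pde3b (1.60), and the adenosine receptor Adora1 (−2.25) and the protein kinase A subunit Prkaca (−1.12) fell. Each of these 8 lipogenesis and lipolysis genes had an adjusted p of at most 8.14e-07.

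In fatty acid uptake and oxidation 18 of 30 genes rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00275, and adjusted p = 0.917 with an estimated correlation). The thioesterases Acot2 (3.97) and Acot1 (4.74), which are near-identical paralogs, lipoprotein lipase (Lpl, 1.82) and Etfdh (1.19), which passes electrons to ubiquinone, rose with adjusted p of at most 4.56e-08. In glycolysis and glucose uptake 12 of 22 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.251). Phosphofructokinase Pfkp (1.91), hexokinase Hk2 (1.34) and Pgk1 (0.99) rose, and the insulin-responsive glucose transporter Slc2a4 fell (−0.96). Few respiratory chain genes passed the test. Of 75 nuclear oxidative phosphorylation subunits 7 rose and 1 fell, with 2 rising adjusted over the list alone (adjusted p = 0.887), while under upper-quartile scaling 1 rose and 30 fell. Cycs (0.81), Uqcrfs1 (0.44) and Atp5b (0.34) rose and Ndufv3 fell (−0.36), a call lost without WT library 2 at 30 °C (−0.28, adjusted p = 0.0866). None of 13 mitochondrially encoded subunits passed the edgeR test, also adjusted over the list alone, with mt-Co1 at 0.04 (SE 0.18) and mt-Cytb at −0.27 (SE 0.17). In the tricarboxylic acid cycle 3 of 25 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.301), and the median of 0.15 turns negative under upper-quartile scaling. Dld (0.62), Idh3a (0.64) and the pyruvate carrier Mpc2 (0.54) rose and Idh2 fell (−0.32). Creatine and calcium cycling had 3 of 12 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.848). The calcium pump Atp2a2 (2.08), the release channel Ryr2 (1.94) and the phosphatase Alpl (0.88) rose, and the receptor Itpr2 fell (−1.198).

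In the unfolded protein and integrated stress response 17 of 26 rose in WT and 3 fell, also adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.591 with an estimated correlation). The transcription factor Atf4 (3.52, SE 0.12), the chaperone Dnajb9 (3.38, SE 0.14) and asparagine synthetase Asns (1.67, SE 0.12) rose. Of 12 heat shock and cold inducible genes 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000202, and adjusted p = 0.183 with an estimated correlation), among them Hsp90aa1 (3.45), Bag3 (2.87), Hspa8 (2.81) and Hsp90ab1 (1.49). In lysosome and lipophagy 13 of 22 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.155 with an estimated correlation), with the proton pump subunit Atp6v1h (2.14), the autophagy protein Gabarapl1 (2.22), Lamp2 (1.55) and the protease Ctsl (1.13) higher. No camera call passed with an estimated correlation after adjustment over the lists, the lowest adjusted p being 0.155. In cholesterol synthesis 5 of 20 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.258). Fdft1 (−2.56), Dhcr7 (−2.17) and Mvk (−1.37) fell.

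Of 18 circadian clock genes all passed the test in WT, 9 higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.838). Arntl (3.83), Cry1 (2.75) and Clock (1.85) rose and Per3 fell (−3.53), and the time of day of tissue collection is not given in the sources used here. In hypoxia and angiogenesis 7 of 16 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.355), with Hif1a (1.28), P4ha2 (1.45) and Angpt2 (1.85) higher and Angpt1 (−3.82) lower. Of 10 sympathetic and neurotrophic genes 4 rose and 3 fell, and 4 and 5 adjusted over the list alone (adjusted p = 0.887, median −0.13 and mean 0.47). The semaphorin Sema3f (3.24) and Nrg4 (0.59) rose and neurturin (Nrtn) fell (−1.71). In adipocyte identity 6 of 16 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.718), with a median of 0.20 that turns negative under upper-quartile scaling. The transcription factor Cebpb (2.72) and Acsl1 (2.26) rose and Cebpa fell (−2.23). Of 14 white adipocyte markers 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.697), with Apcdd1 (−3.88), Hoxa9 (−4.58) and Lep lower and Npr3 (2.54) higher.

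Markers of other cells also moved with cold in WT. Macrophage markers had 11 of 22 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.113), with Cd163 (2.23), Clec10a (2.39), Gpnmb (3.25) and Itgam (1.497) higher. T and B lymphocyte markers had 6 of 18 lower, 4 adjusted over the list alone (adjusted p = 0.252), including Cd79a (−2.95), Cd247 (−2.77) and Ighd (−2.33). Of 5 neutrophil markers 2 fell, 1 adjusted over the list alone (adjusted p = 0.355), namely Elane (−4.21) and S100a8 (−1.38). Without WT library 4 at 4 °C Cd247 was at −3.84, Ighd at −3.43 and Elane at −5.44. The call of S100a8 was lost without WT library 1 at 30 °C (−0.91, adjusted p = 0.251) and, at −1.43 to −1.09 with adjusted p from 0.0516 to 0.124, without WT library 2 or AdC3KO library 1, 2 or 3 at 30 °C or WT library 2, 3 or 4 or AdC3KO library 4 at 4 °C. Endothelial markers had 9 of 15 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.355), with Sox17 (3.09) and the tight junction protein Cldn5 (2.84) higher and Erg (−1.37) and Tie1 (−1.09) lower. Fibroblast and extracellular matrix genes had 7 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.869), with a median of 0.04 that turns negative under upper-quartile scaling. Lox (1.42) and Postn (0.91) rose and Col6a1 (−0.66) and Col6a2 (−0.63) fell. Smooth muscle and pericyte markers had 4 of 11 higher and 4 lower, 5 and 4 adjusted over the list alone (adjusted p = 0.838), with Des (0.91) higher and Cspg4 (−2.08), Notch3 (−1.34) and Myh11 (−0.99) lower. Schwann cell and nerve markers had 1 of 10 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.142), with Ngfr (−5.20) and Mbp (−0.87) lower and Cdh19 (0.77) higher. Red blood cell transcripts had 4 of 6 higher, 5 adjusted over the list alone (adjusted p = 0.215), with Alas2 (0.75), Hbb-bt (0.72), Hbb-bs (0.68) and Hba-a1 (0.55). The call of Hbb-bt was lost without WT library 1 or 3 at 30 °C or WT library 1 or 2 at 4 °C (log2 fold change 0.51 to 0.70, adjusted p from 0.058 to 0.0996).

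Skeletal muscle markers had 1 of 18 lower in WT, also adjusted over the list alone (adjusted p = 0.478), which was Myl1 (−0.66). Cell cycle genes had 1 of 23 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.972), Tyms (0.79) and Mcm2 (−1.33), and their median of 0.17, which turns negative under upper-quartile scaling, and mean of 0.13 stood against a camera direction of down. Interferon response genes had 2 of 21 higher, 0 adjusted over the list alone by edgeR (adjusted p = 0.838), which were Oas2 (1.88, SE 0.62) and Oas3 (3.70, SE 1.39). Oas3 was 32.9 CPM in WT library 4, the library highest in interferon genes. Without that library Oas3 was at 1.51 (adjusted p = 0.178) and Oas2 at 1.10 (adjusted p = 0.0410). The call of Oas3 was also lost without WT library 1, 2 or 3 or AdC3KO library 2 at 30 °C (3.53 to 3.84, adjusted p from 0.0529 to 0.109), and that of Oas2 without WT library 2 (1.73, adjusted p = 0.0715) or 3 (1.85, adjusted p = 0.0623) at 30 °C.

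**Figure D4:**
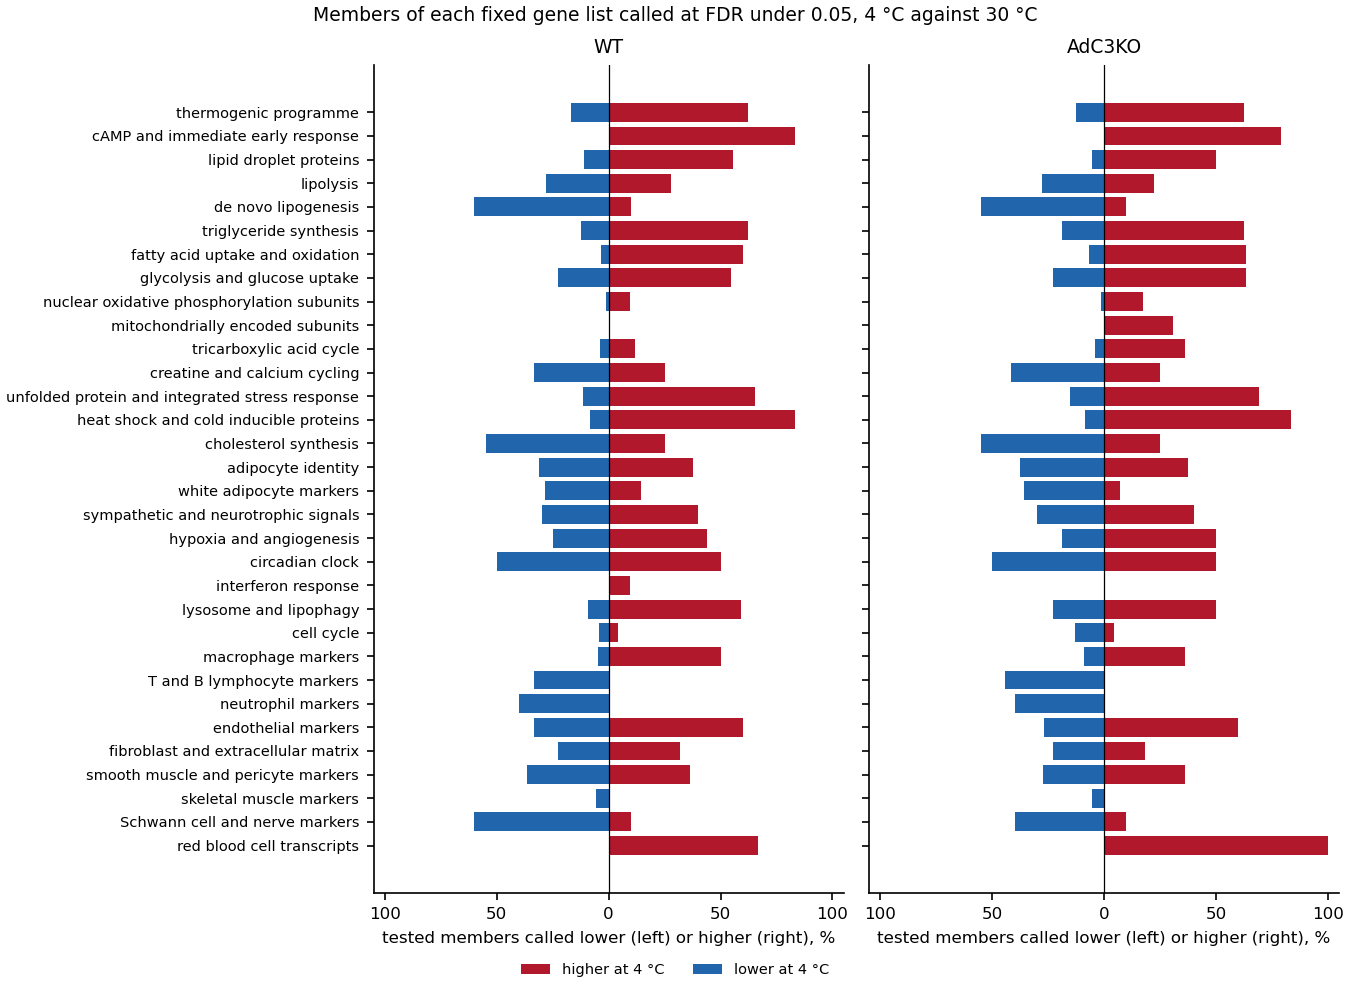
Share of the tested members of each of the 32 gene lists called higher (red, right) or lower (blue, left) at 4 °C than at 30 °C at an adjusted p below 0.05, in WT and in AdC3KO, in percent. The cyclic AMP and immediate early list had 20 of 24 members higher in WT and 19 in AdC3KO, and under upper-quartile scaling the median of 5 lists in WT and 4 in AdC3KO changed sign.

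In AdC3KO BAT Ucp1 was 8.49-fold higher at 4 °C, at 13734 ± 1703 CPM (SD, n = 4) against 1618 ± 370.1 CPM (SD, n = 3). Dio2 went from 17.2 to 3617 ± 298 CPM, Ppargc1a from 47.1 to 1109 ± 301 CPM and Plin2 from 286 to 4078 ± 303 CPM. Lep fell from 126 ± 54.4 to 0.965 ± 0.718 CPM and Dgat2 from 1905 ± 253 to 224 ± 18.1 CPM. By camera at the preset correlation 7 lists differed, and none of them did with an estimated correlation after adjustment over the lists (lowest adjusted p 0.219). By fry, against no change, 20 of 32 passed, with these 7 among them.

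In AdC3KO 4937 genes were higher and 5113 lower, of which 2241 and 3177 by at least 2-fold. The groups did not overlap for 9506 of them and for 64.1% of all genes, where chance gives 5.71%. DESeq2 called 10372 and shared 9849. The median log2 fold change was −0.06, moved to −0.29 by upper-quartile scaling, with 3737 higher and 6542 lower (36.4% higher against 49.1%). Without the libraries with muscle transcripts AdC3KO at 30 °C keeps 1 library, so no count is given.

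Mfsd2a had 1 count at 30 °C and 17023 at 4 °C in AdC3KO (depth-scaled ratio 15274, counting interval 2741 to 603334). Slco1a1 had 2 counts at 30 °C (ratio 887, counting interval 245 to 7325), and Acot5 had 0 and was at least 349.7-fold higher. Elovl3 (log2 fold change 8.73, SE 0.40), Fgf21 (8.34, SE 0.56), Dio2 (7.72, SE 0.22), Nr4a3 (7.55, SE 0.59), the potassium channel subunit Kcne4 (6.65), placental growth factor Pgf (6.45) and Bean1 (6.44) followed, each with an adjusted p of at most 5.12e-07. The largest falls were in Lep (−6.98, SE 0.59), Hcar1 (−6.18, SE 0.52), Aplnr (−5.96, SE 0.26), Gdf5 (−5.64), Klhdc7a (−5.21), the GTPase Rab17 (−5.04), the Wnt inhibitor Apcdd1 (−5.01), Ripor3 (−4.99), Akap5 (−4.59) and Bahcc1 (−4.35), with an adjusted p of at most 0.000135. Without AdC3KO library 3 at 30 °C the fold moved by over 1.5 times for Bean1 (7.95) and Fgf21 (8.96). Without library 2 there it did for Mfsd2a (15.1) and Slco1a1 (12.0), and without library 1 at 4 °C for Rab17 (−6.51). Of the 7112 eligible genes, 321 lacked a regular symbol.

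The thermogenic list had 15 of 24 genes higher and 3 lower in AdC3KO, and 15 and 4 adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.328 with an estimated correlation). Ucp1 (3.09, SE 0.18), Ppargc1a (4.56, SE 0.27) and Gk (5.22, SE 0.15) rose, with adjusted p of at most 3.88e-09, and Cidea was at −0.32 (SE 0.14, adjusted p = 0.0567). The cyclic AMP and immediate early list had 19 of 24 higher and none lower, also adjusted over the list alone (adjusted p = 4.88e-07, and adjusted p = 0.219 with an estimated correlation), with Gadd45g (5.15), Sik1 (4.28), Dusp1 (3.70) and Crem (2.17). S100b was at −0.02 (SE 0.22, adjusted p = 0.933).

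Lipid droplet proteins had 9 of 18 higher and 1 lower in AdC3KO, also adjusted over the list alone (adjusted p = 0.169). Plin2 (3.84, SE 0.16), Fitm2 (1.62) and Plin4 (1.42) rose and Plin3 fell (−2.69, SE 0.08), while Cidec was at 0.08 (SE 0.19, adjusted p = 0.716) and Plin1 at −0.05 (SE 0.16, adjusted p = 0.805). Triglyceride synthesis had 10 of 16 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.0397, and adjusted p = 0.771 with an estimated correlation), with Dgat1 (2.27) and Gpam (1.89) higher and Dgat2 (−3.09) lower. De novo lipogenesis had 2 of 20 higher and 11 lower, also adjusted over the list alone (adjusted p = 0.0397, and adjusted p = 0.771 with an estimated correlation), with Srebf1 (−3.25), Mid1ip1 (−2.18), Pnpla3 (−2.002) and Mlxipl (−1.94). The lipogenesis call was lost without WT library 2 (0.0529) or AdC3KO library 3 (0.0734) at 4 °C, and that of triglyceride synthesis without AdC3KO library 3 at 4 °C (0.0566). Lipolysis had 4 of 18 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.831), with Abhd5 (2.10), Pde3b (1.30), Adora1 (−2.61) and Prkaca (−1.24). Fatty acid uptake and oxidation had 19 of 30 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.771 with an estimated correlation), with Acot1 (4.10), Acot2 (3.76), Lpl (1.99) and Etfdh (1.198).

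Glycolysis and glucose uptake had 14 of 22 higher and 5 lower in AdC3KO, also adjusted over the list alone (adjusted p = 0.0848), with Pfkp (2.30), Hk2 (1.59) and Pgk1 (1.09) higher and Pfkfb1 (−2.71) lower. Nuclear oxidative phosphorylation subunits had 13 of 75 higher and 1 lower, and 7 and none adjusted over the list alone (adjusted p = 0.0671), and the median of 0.16 turns to −0.07, with 3 higher and 7 lower, under upper-quartile scaling. Cycs (0.98), Uqcrfs1 (0.55), Uqcrh (0.53) and Uqcrc2 (0.41) rose. Mitochondrially encoded subunits had 4 of 13 higher, 1 adjusted over the list alone (adjusted p = 0.335). These were mt-Atp6 (1.81), mt-Co3 (1.78), mt-Nd4l (1.74) and mt-Nd3 (1.66), which averaged 17.7, 23.2, 1.79 and 1.79 CPM at 30 °C in AdC3KO where mt-Co1 averaged 94493 CPM, and copies of mitochondrial sequence in the nuclear genome can share their reads. The calls of mt-Atp6, mt-Co3 and mt-Nd4l were lost without any AdC3KO library at 30 °C or AdC3KO library 1 or 2 at 4 °C (log2 fold change 1.24 to 1.87, adjusted p from 0.0735 to 0.116), and that of mt-Nd4l also, at 1.74 to 1.76, without WT library 3 at 30 °C (0.0546) or WT library 2 (0.0529) or 4 (0.0501) at 4 °C. The tricarboxylic acid cycle had 9 of 25 higher and 1 lower, 7 and none adjusted over the list alone (adjusted p = 0.0671), with a median of 0.22 that turns negative under upper-quartile scaling, and Idh3a (0.82), Mpc2 (0.75), Dld (0.70) and Fh1 (0.53) rose. Creatine and calcium cycling had 3 of 12 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.83, median −0.17 and mean 0.41), with Ryr2 (2.80), Atp2a2 (2.16), Alpl (0.79) and Itpr2 (−1.38).

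The unfolded protein and integrated stress response had 18 of 26 higher and 4 lower in AdC3KO, also adjusted over the list alone (adjusted p = 0.000721, and adjusted p = 0.771 with an estimated correlation), with Atf4 (3.68), Dnajb9 (3.18) and Asns (1.53). Heat shock and cold inducible genes had 10 of 12 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.000221, and adjusted p = 0.254 with an estimated correlation), with Hsp90aa1 (3.60), Hspa8 (3.06), Bag3 (2.92) and Hsp90ab1 (1.52). Lysosome and lipophagy had 11 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.0671), with Atp6v1h (2.27), Gabarapl1 (2.11), Lamp2 (1.61) and Ctsl (1.14). After adjustment over the lists the lowest p with an estimated correlation was 0.219. Cholesterol synthesis had 5 of 20 higher and 11 lower, and 5 and 12 adjusted over the list alone (adjusted p = 0.285), with Fdft1 (−2.69), Dhcr7 (−1.97) and Mvk (−1.43). All 18 clock genes passed again, 9 higher and 9 lower, also adjusted over the list alone (adjusted p = 0.76), with Arntl (3.85), Cry1 (2.50), Per3 (−4.03) and Dbp (−3.44). Hypoxia and angiogenesis had 8 of 16 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.269), with Hif1a (1.18), P4ha2 (1.73), Angpt2 (2.03) and Angpt1 (−3.78). Sympathetic and neurotrophic genes had 4 of 10 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.76), with a median of 0.19 that turns negative under upper-quartile scaling, and with Sema3f (3.35), Ntf3 (−1.67) and Nrtn (−1.27). Adipocyte identity had 6 of 16 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.76, median −0.09 and mean 0.16), with Cebpb (2.94), Acsl1 (1.81) and Cebpa (−2.69). White adipocyte markers had 1 of 14 higher and 5 lower, 1 and 4 adjusted over the list alone (adjusted p = 0.27), with Npr3 (2.88), Lep, Apcdd1 and Hoxa9 (−3.65).

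Among markers of other cells in AdC3KO, macrophage markers had 8 of 22 higher and 2 lower, 4 and 1 adjusted over the list alone (adjusted p = 0.368), with Cd163 (1.76), Clec10a (1.85), Itgam (1.56) and Cd68 (1.10). T and B lymphocyte markers had 8 of 18 lower, also adjusted over the list alone (adjusted p = 0.0671), with Cd247 (−3.53, and −4.30 without AdC3KO library 1 at 4 °C), Ighd (−3.004), Cd79a (−2.51) and Cd79b (−2.28). Neutrophil markers had 2 of 5 lower, also adjusted over the list alone (adjusted p = 0.368), Elane (−3.91, and −7.45 without AdC3KO library 3 at 4 °C) and Mmp9 (−1.32). Endothelial markers had 9 of 15 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.123), with Sox17 (3.35), Cldn5 (2.97), Pecam1 (1.43) and Kdr (1.24). Fibroblast genes had 4 of 22 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.964, median −0.05 and mean 0.03), with Lox (1.76), Col6a3 (−0.88), Col6a1 (−0.73) and Col6a2 (−0.68). Smooth muscle and pericyte markers had 4 of 11 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.964), with a median of 0.23 that turns negative under upper-quartile scaling, and with Des (1.28), Cspg4 (−1.96), Notch3 (−1.33) and Pdgfrb (−0.74). Schwann cell and nerve markers had 1 of 10 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.269), with Ngfr (−5.38, and −6.09 without AdC3KO library 1 at 4 °C), Sox10 (−1.73) and Mbp (−0.81). All 6 red blood cell transcripts were higher, also adjusted over the list alone (adjusted p = 0.0619), with Hbb-bt (1.06), Hbb-bs (0.98), Hba-a1 (0.87) and Alas2 (0.85). Skeletal muscle markers had 1 of 18 lower (Myl1, −0.45) and 0 adjusted over the list alone by edgeR, with a camera direction of down (adjusted p = 0.647) against a median of 1.53. Cell cycle genes had 1 of 23 higher and 3 lower, 1 and 1 adjusted over the list alone (adjusted p = 0.725), with Tyms (1.01), Mcm5 (−1.53), Mcm2 (−1.46) and Aurka (−0.97). None of 21 interferon genes passed the edgeR test, also adjusted over the list alone (adjusted p = 0.686), with Bst2 at 0.27 (SE 0.80). The call of Aurka was lost without any AdC3KO library at 30 °C or AdC3KO library 2, 3 or 4 at 4 °C (log2 fold change −1.06 to −0.77, adjusted p from 0.0547 to 0.101). That of Myl1 (−0.36 to −0.34, adjusted p from 0.0527 to 0.0734) was lost without AdC3KO library 3 at 30 °C or AdC3KO library 1 or 2 at 4 °C.

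Whether the response to cold differed between genotypes was tested by the interaction, and no single gene passed. Across all tested genes the responses of WT and AdC3KO ran in parallel, with a Pearson r of 0.923, a Spearman rho of 0.924 and a slope of 1.01, where genes are not independent replicates and no p is given. Both genotypes shared 4443 higher and 4413 lower genes, where independent calls would share 1510.3 and 1573, and 0 genes were called in opposite directions by edgeR. The effects of genotype at 30 °C and 4 °C, in contrast, had an r of 0.0617 and a rho of 0.0301 over all genes, and an r of 0.904 over the 9 genes called at either temperature. Without 1 library the r over all genes of the genotype effects lay between −0.0249 (WT library 1 at 30 °C) and 0.202 (WT library 3 at 30 °C), with 0.00269 without WT library 2, −0.00269 without AdC3KO library 1 and 0.00700 without AdC3KO library 3 at 30 °C, and it was 0.220 in a new fit with a filter at 5 CPM and 0.254 over the 10417 genes past 5 CPM in the fit of all genes.

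**Figure D5:**
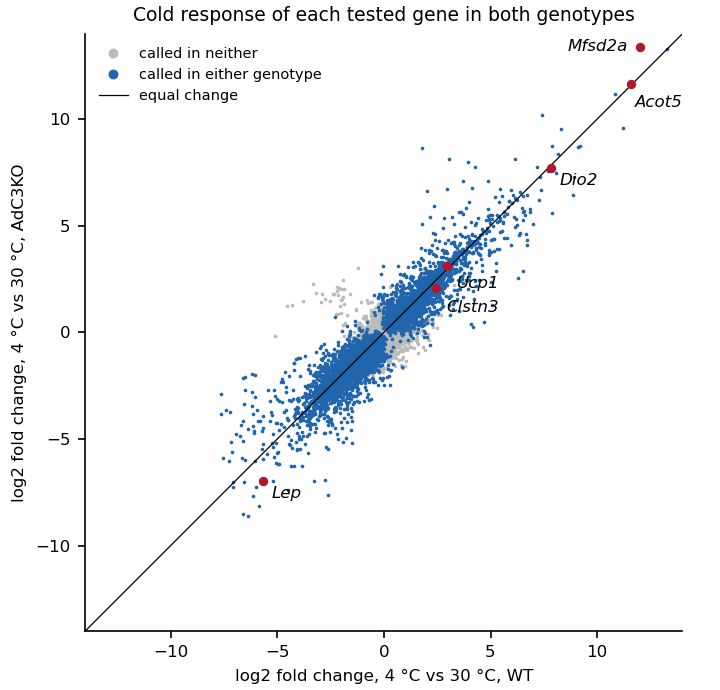
Log2 fold change of 4 °C against 30 °C of each tested gene in WT (horizontal) and AdC3KO (vertical), blue where called in either genotype and grey where called in neither, with the line of equal change and 6 genes marked in red. The responses correlate with a Pearson r of 0.923 over 15949 genes, and fitted values of genes with few counts at 30 °C, such as Mfsd2a and Acot5, depend on the prior count.

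The edgeR test of the interaction called 0 genes, with 349 at an unadjusted p below 0.05, and DESeq2 called 0, with 455. The estimate, AdC3KO response minus WT response, was −0.37 for Clstn3 (SE 0.19), 0.12 for Ucp1 (SE 0.22), 0.05 for Ppargc1a (SE 0.31), −0.10 for Dio2 (SE 0.23) and 0.06 for Cidea (SE 0.20). It was −0.39 for Cidec (SE 0.27), −0.24 for Plin1 (SE 0.22), 0.16 for Fgf21 (SE 1.21), 0.83 for Elovl3 (SE 0.58) and 0.46 for S100b (SE 0.31). Each had an adjusted p of 1.

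By camera 9 lists differed in their response, none with an estimated correlation after adjustment (adjusted p of at least 0.719), and the lowest adjusted p by fry, against no change, was 0.815. Higher in AdC3KO were nuclear oxidative phosphorylation subunits (adjusted p = 1.55e-09, and adjusted p = 0.733 with an estimated correlation; Atp5b 0.06, Atp5a1 0.09), mitochondrially encoded subunits (9.57e-05, and adjusted p = 0.719; mt-Co1 0.05, mt-Cytb 0.26) and endothelial markers (0.000791, and adjusted p = 0.719; Kdr 0.34, Cdh5 0.41). Also higher were glycolysis genes (adjusted p = 0.00978, and adjusted p = 0.719 with an estimated correlation, Aldoa 0.28 and Eno1 0.11), tricarboxylic acid cycle genes (0.00978, and adjusted p = 0.744, Ogdh 0.08), red blood cell transcripts (0.00978, and adjusted p = 0.719, Hbb-bs 0.30 and Hba-a1 0.31) and cyclic AMP and immediate early genes (0.0371, and adjusted p = 0.719, Gadd45g −0.14 and Irf4 −0.09). Lower were macrophage markers (adjusted p = 0.0056, and adjusted p = 0.719 with an estimated correlation, Lyz2 −0.59 and C1qb −0.55) and white adipocyte markers (0.0371, and adjusted p = 0.719, Npr3 0.34 and Lep −1.30). No member of any list was called in the interaction by edgeR. Leaving out 1 library ended 7 of the 9 calls, all but those of nuclear and mitochondrially encoded subunits. At 30 °C these losses came without WT library 1 (endothelial 0.107, cyclic AMP 0.444, white adipocyte 0.143), WT library 2 (glycolysis 0.101, tricarboxylic acid cycle 0.29), WT library 3 (white adipocyte 0.0775), AdC3KO library 1 (cyclic AMP 0.155, tricarboxylic acid cycle 0.0547) and AdC3KO library 2 (cyclic AMP 0.115, glycolysis 0.132, tricarboxylic acid cycle 0.193, macrophage 0.121, white adipocyte 0.364). At 4 °C they came without WT library 1 (cyclic AMP 0.0644), WT library 2 (glycolysis 0.126, tricarboxylic acid cycle 0.104), WT library 3 (cyclic AMP 0.0507, white adipocyte 0.0628), WT library 4 (cyclic AMP 0.0778, tricarboxylic acid cycle 0.173, red blood cell 0.173, macrophage 0.0912), AdC3KO library 2 (white adipocyte 0.0819) and AdC3KO library 3 (cyclic AMP 0.372, tricarboxylic acid cycle 0.0708).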

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

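The measure of a library far from the rest of its group and the test of lists for the interaction were set before the data were examined, while Kng2, Rfc4, Gm8134, Eif4a1, Adipoq, Gm44006, 1700027F06Rik, Oaz2-ps, Cyb5r4, Me1 and Oaz2 were added to the genes of the first after their values were seen. In each group of 4 libraries at 4 °C the gap between the most extreme library and the nearest other was divided by the range of the group, for library measures, list means and 220 genes, and compared with Dixon's critical value. Groups of 3 libraries, at 30 °C, were not tested. The gap was above the critical value in 40 of 520 comparisons, where chance alone gives about 1 in 20, which is 26.

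WT library 1 at 4 °C stood apart in 9 values, given with the range of the other 3 libraries. Its 10 most abundant genes held 25.3% of counts (others 23.0% to 23.2%), and its mean log2 CPM was 2.34 for white adipocyte markers (2.14 to 2.17) and 5.07 for clock genes (5.13 to 5.14). Its CPM was 1239.8 for Cidec (622 to 713), 42201 for mt-Cytb (29761 to 31015), 751 for Angptl4 (497 to 521), 1461 for Cycs (1198 to 1224), and 0.0589 for Gm44006 and 0.177 for 1700027F06Rik, which are listed at 0 in the others. WT library 2 had a mean log2 CPM of skeletal muscle markers of 1.54 (−1.65 to −1.30), with Myh4 at 15.5 CPM (0 in the others) and Hsp90ab1 at 3609 CPM (2736 to 2818). WT library 3 had Dgat1 at 788 CPM (722 to 729.7). In WT library 4, with 9 values, haemoglobin transcripts held 0.0303% of counts (0.0457% to 0.0488%) and cell cycle genes had a mean log2 CPM of 2.03 (0.43 to 0.68). Its CPM was 0.122 for Kng1 (0.0475 to 0.0589), 213 for Bst2 (22.0 to 32.2), 12.2 for Mcm6 (4.30 to 5.03), 90.5 for C1qb (40.8 to 44.6), 75.5 for Sgk2 (100.6 to 103), 0.408 for Samd5 (0.471 to 0.475) and 32.9 for Oas3 (1.18 to 2.78).

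AdC3KO library 1 at 4 °C stood apart in Bst2 at 91.5 CPM (others 23.1 to 27.3), Oas3 at 13.3 CPM (1.35 to 2.37) and Hbb-bs at 294 CPM (357 to 360.0). AdC3KO library 2 did so in Dio2 at 4064 CPM (3453 to 3481), Atp2a2 at 1121 CPM (808 to 836), Pcna at 51.7 CPM (42.6 to 43.4), Mbp at 15.6 CPM (21.8 to 22.7), Cebpa at 68.0 CPM (107 to 115) and Eif4a1 at 717 CPM (638.9 to 639.6). AdC3KO library 3, with 8 values, had a mean log2 CPM of 4.26 for creatine and calcium cycling (3.55 to 3.57), 9.99 for adipocyte identity (9.63 to 9.68) and 4.65 for skeletal muscle markers (−1.51 to −1.43). Its CPM was 767 for Cidec (608 to 627), 478 for Col3a1 (349 to 365), 149 for Des (91.8 to 98.3), 141 for Myh4 (0 in the others) and 0.244 for Elane (0 in the others). AdC3KO library 4 had Per3 at 8.09 CPM (4.89 to 5.42).

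The cold response of 9 lists differed between genotypes in the interaction test by camera at the preset correlation, and no explanation was tested for these differences. The adjusted p was 1.55e-09 for nuclear oxidative phosphorylation subunits, 9.57e-05 for mitochondrially encoded subunits, 0.000791 for endothelial markers, 0.0056 for macrophage markers, 0.00978 each for glycolysis, the tricarboxylic acid cycle and red blood cell transcripts, and 0.0371 each for cyclic AMP and immediate early genes and white adipocyte markers. None passed with an estimated correlation (lowest adjusted p 0.719) or, against no change, by fry (0.815), and no gene of these lists passed alone by edgeR.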

How the results depend on the processing

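Leaving out the libraries high in interferon genes, the libraries with skeletal muscle transcripts, or the genes of chromosomes 6, 9 and 16 was chosen after the data were seen, and the other alternatives were set before. In all 29 alternatives run for it, Clstn3 kept its direction, and its call wherever a test was run, with a log2 fold change of −3.86 to −3.63 for genotype at 30 °C, −4.16 to −3.98 at 4 °C, 2.07 to 2.50 for cold in WT and 1.66 to 2.16 for cold in AdC3KO. The genes past the threshold for cold in WT numbered 7538 to 10274 against 9787, and 8957 to 9804 without 1 library. For cold in AdC3KO they numbered 6589 to 10538 against 10050, 9225 to 10318 without 1 library, and 6589 without the 5 libraries with skeletal muscle transcripts, where fewer libraries remain and AdC3KO at 30 °C keeps 1, assumed to vary like the other groups. For the interaction the number was 0 in each alternative but the skeletal muscle covariate, with 1 lower gene, Myh4 (adjusted p = 0.000134), which was named after its value was seen and belongs to the list that makes the covariate. No call of a named gene reversed. Of the results of called genes under an alternative, 3599 kept their call and 83 lost it for cold in WT, 3653 and 80 for cold in AdC3KO, 136 and 29 for genotype at 30 °C and 179 and 14 at 4 °C. For called lists these were 112 and 7, 109 and 10, 34 and 17, and 121 and 32, and 110 and 43 for the interaction.

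The few genes that differed by genotype depended more on the processing, against 7 at 30 °C and 8 at 4 °C. With a filter at 5 CPM, which tests fewer genes, there were 4 and 5. Without the libraries with skeletal muscle transcripts there were 3 at 4 °C (Clstn3, Kng1 and Pex5), where fewer libraries remain. At 30 °C AdC3KO keeps 1 library in that fit, so no count is given. Without the genes of chromosomes 6, 9 and 16, which leaves out called genes, there were 2 at each temperature. A fit of the compared groups alone gave 5 at 4 °C, 5 of them shared, and DESeq2 gave 22, 8 of them shared, and the cause was not tested. Without 1 library there were 4 to 7 at 30 °C (4 without WT library 1 and without WT library 3) and 7 to 9 at 4 °C. Without the libraries with skeletal muscle transcripts Pex5 had a log2 fold change of 0.99 at 30 °C (adjusted p over all alternatives 2.5e-17 to 0.563). Eif4a2 (0.61) lost it at 4 °C against a 1.2-fold change (adjusted p = 0.122), in the compared groups alone (0.0657, log2 fold change 0.61) and without those libraries (0.459, log2 fold change 0.56, over all alternatives 3.5e-14 to 0.832). Gm44007 (5.06) lost it in the compared groups alone (0.143, log2 fold change 5.05) and without those libraries (0.784, log2 fold change 4.93, over all alternatives 6.7e-14 to 0.784). Zfp949 (0.84) lost it at 4 °C against a 1.2-fold change (0.0673), in the compared groups alone (0.208, log2 fold change 0.84) and without those libraries (0.459, log2 fold change 0.91, over all alternatives 6.5e-07 to 0.459).

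The replicate numbers were not taken as pairs, since no comparison had 3 or more pairs that all correlated above 0.1 after removal of the group means. Libraries that share a title number correlated at −0.400 to 0.0764. Of those that share a description number, the 2 pairs of WT across temperature had 0.172 and 0.238, each library being the best partner of the other, the 3 pairs of genotypes at 4 °C had 0.0967 to 0.135, and the others had −0.399 to 0.0764. With these numbers as a block, genotype at 30 °C had 4 genes by title number and 2 by description number, and the cause was not tested beyond the degrees of freedom that the block takes. At 30 °C the calls of Eif4a2 (adjusted p = 0.411 by title and 1 by description number, log2 fold change 0.62 and 0.59), Ankdd1a (0.165 and 0.602, log2 fold change 3.65 and 3.97) and Gm7049 (0.0926 and 0.563, log2 fold change 3.72 and 3.21) were lost with both numbers, and those of Pex5 (0.563, log2 fold change 0.92) and Gm11868 (0.0833, log2 fold change 4.39) with the description number. At 4 °C that of Eif4a2 (0.0996 and 0.832, log2 fold change 0.61 and 0.62) was lost with both and that of Zfp949 (0.368, log2 fold change 0.96) with the description number. The number at 4 °C was 10 and 6, for cold in WT 9415 and 8151 and for cold in AdC3KO 9652 and 9756.

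The correlation of the cold responses, 0.923, was 0.948 over genes called in either genotype, 0.976 in a new fit with a filter at 5 CPM (0.977 over the 10417 genes past 5 CPM in the fit of all genes) and 0.895 to 0.925 without 1 library. That of the genotype effects, 0.0617, was 0.904 over genes called at either temperature, which are chosen for their effect, 0.220 in a new fit with a filter at 5 CPM (0.254 over those 10417 genes) and −0.0249 (without WT library 1 at 30 °C) to 0.202 (without WT library 3 at 30 °C). Only 20.9% of simulated 1.5-fold changes were found for genotype at 30 °C, 37.3% at 4 °C and 7.46% for the interaction. With fewer real calls, stricter adjustment lowers recovery.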

Other observations

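Of the tests in this part, only that of extra copies of the chromosome 9 interval was set before its result was seen, and the others were chosen after. Those on windows of chromosome 9, on chromosome 6 and on splits for the interaction were rewritten after earlier forms of them had given values. Genes named here that no other part names were chosen after their values were seen.

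Genes of chromosome 9 differed by genotype at both temperatures. Of 27 genes with an unadjusted p below 0.05 and the same direction at both temperatures (4.98 if independent, with 4 in opposite directions), 16 lay on chromosome 9 between 44134469 and 101251795, 9 higher and 7 lower in AdC3KO, where the chromosome holds 5.61% of tested genes. The genes on it at 1 CPM or more had an r of 0.330 between the genotype effects over their SE, against 0.0833 for other chromosomes and at most 0.217 in 10000 runs of as many neighbouring genes elsewhere, with 0.865 in the window from 80 to 90 Mb, which held 6 of the 16 genes, and 0.234 without that window. The tables argue against a response to the loss of Clstn3b wherever genes lie, since 5 of 13 windows of 10 Mb on the chromosome held such a gene against 6 of 260 elsewhere (one-sided Fisher p times the 20 chromosomes, 0.000839), and against extra copies of the interval, whose 335 genes had a median log2 fold change of 0.0036 (SE 0.0081) at 30 °C and −0.0047 (SE 0.0115) at 4 °C, or of that window alone (28 genes, −0.0164, SE 0.0292, and −0.0849, SE 0.0519). A strain variant against the reference, inherited with the genotype, stays open, and the strain background is not given. Of 4 pseudogenes elsewhere that differed at both temperatures, 3 match parents on chromosome 9 (Gm11868 to Cyb5r4, Gm7049 to Me1, Oaz2-ps to Oaz2). Of all 336 with a match, 24 do. The one-sided Fisher p = 0.00123 counts Cyb5r4 and Me1, both at 80 to 90 Mb, as independent and is too low.

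On chromosome 16, Kng2, Kng1, Gm8134, Eif4a2 and Rfc4, between 22985854 and 23127737, were higher in AdC3KO at both temperatures with an unadjusted p below 0.05, Kng2 by a log2 fold change of 0.43 and 0.53 and Rfc4 by 0.76 and 0.69. The neighbouring Adipoq was at 0.04 (SE 0.22) and 0.10 (SE 0.19). At 30 °C the tables argue against reads shared with the paralog Eif4a1, which differed by 4.48 CPM (SE 15.2) where Eif4a2 was 194 CPM (SE 19.5) higher. The test was split by temperature after its values were seen, with a looser bound at 4 °C. There Eif4a1 differed by −1.57 CPM (SE 52.3) where Eif4a2 was 341 CPM (SE 39.8) higher. This argues against shared reads as the source of most of the gain. Under the bound of 30 °C these values would not decide, since the SE of Eif4a1 is wide. Extra copies of the segment, as a transgene built on this neighbourhood may carry, cannot be told apart from a constant gain in Eif4a2, because the interaction of −0.0084 (95% interval −0.281 to 0.264) leaves out neither 0 nor the −0.242 of a constant gain. Which transgene the mice carry is not given in the sources used here, and a response of these genes to the loss of Clstn3b stays open and untested.

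On chromosome 6, Pex5 and 3 transcripts beyond it, downstream of Clstn3 on its strand, were higher in AdC3KO at 4 °C, namely Gm44007 (log2 fold change 5.06), Gm44006 (6.86) and 1700027F06Rik (5.10), of which edgeR called Gm44007 (adjusted p = 0.00339) and DESeq2 called Gm44007 and Gm44006 (adjusted p = 0.0336). At 30 °C Gm44007 averaged 0.0276 CPM in WT and 0.0712 CPM in AdC3KO, and the other 2 transcripts are listed at 0 in both genotypes. The tables argue against read-through of a constant share of Clstn3 transcription into the transcripts beyond Pex5, because their summed gain at 30 °C was 0.0436 CPM (SE 0.0278) where the gain at 4 °C of 11.4 CPM (SE 3.95) and the cold ratio of Clstn3 in WT (5.37) would give 2.11 CPM (SE 0.736), and 2.73 CPM (SE 0.951) by the ratio in AdC3KO (4.16). For Pex5, which gained 93.9 CPM (SE 7.48) at 30 °C and 388 CPM (SE 29.7) at 4 °C, a ratio of 4.13, such read-through and a proportional rise cannot be told apart, since the interaction of 0.26 (95% interval −0.03 to 0.55) leaves out neither the 0.27 of the first nor the 0 of the second. Read-through that reaches further in the cold, another effect of the altered locus on its neighbours and a response to the loss of Clstn3b stay open and untested, and the strand setting of the counts is not given in the sources used here although Gm44006 lies on the other strand.

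The libraries of each comparison were also split in other ways into groups of the same sizes. For cold, only the real split gave as many genes in WT (1 of 35, with 9787 and at most 6422 in the others) and in AdC3KO (1 of 35, with 10050 and at most 5660). This share is below 0.05 and is the smallest that these group sizes allow. For genotype at 30 °C the 10 splits are too few for a share below 0.05, and 2 of 10 gave as many genes (7, and at most 7 in the others, in the split that sets the 3 libraries with skeletal muscle transcripts against the rest). For genotype at 4 °C chance is not excluded for the number of genes, since 2 of 35 splits gave 8 or more. The highest other, 300, set WT libraries 1 and 3 and AdC3KO libraries 2 and 3 against the rest, and this points to a structure of the samples whose cause was not tested. For the interaction the real number is 0, which all 100 of the 100 splits drawn from 700 reach (at most 2), so the splits say nothing about chance.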
